A study of Homo sapiens with 2 samples.

How the data were processed

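RNA was measured in 2 libraries of the LM3 line, 1 per genotype, grouped by the genotype given in the labels. Per the labels' protocols, poly-A RNA was enriched, libraries had 12 cycles of PCR, and sequencing gave paired ends of 100 bases. The submitters' processing notes name the genome build hg38 and Bowtie 0.12.2, without a role. Values were deposited by the authors as FPKM, per the file headers, in 1 table per library, with 1 value for each transcript start, transcript end or splicing event of a gene locus. The program that made the events, its annotation, its filters and its use of strand are not given in the sources used here. The tables hold no read counts, so depth and counting error are unknown and no interval could be given.

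The tables list 20 types of event, in 32700 loci for wild type and 32719 for the knockout-labelled library. Events of a locus overlap, and their values repeat, so they cannot be added across types. The plan made before the data were examined was to add the values of each gene, assuming that a gene's values were those of separate transcripts. Instead a gene's value was the largest of the sum over its start events, the sum over its end events and its largest single event. Events are listed incompletely: start and end sums agreed within 5% in 51.2% of loci, so a gene's value can be too low in either library and a ratio can come from a listing difference. An exact 0 can be a failed estimate, because genes that every cell uses, such as HSPE1, are listed at 0 in 1 library. Such genes are described as listed at 0, with no fold. A gene with no assigned event in 1 library was also given 0 there and is described in the same way. Of 33629 genes named in either library, 33268 were named in both. In loci of several genes an event went to the gene whose exon boundary in GENCODE 29 lay at its junction; 2.45% of wild-type and 2.42% of knockout-labelled events could not be assigned. Of the junctions of start and end events, 98.3% lay at GENCODE 29 exon boundaries in both libraries.

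The log2 ratio of a gene was log2 of knockout-labelled FPKM + 1 over wild-type FPKM + 1, which understates the change of low genes. A gene was measured where the larger FPKM was at least 1. With 1 library per genotype no test was possible, and a gene was called higher or lower by size alone, at 2-fold or more. The 23 gene lists were fixed before the data were examined: mesenchymal and epithelial markers, migration, TGF-beta, Wnt, replication, mitosis, cell cycle inhibitors, hepatocyte markers, estrogen receptor, NF-kB, interferon, ATF4, hypoxia, cholesterol and fatty acid synthesis, histones, mitochondrially encoded genes, immediate early genes, fibroblast, endothelial and leukocyte markers, coregulators and neighbours of NCOA5. A list with at least 3 measured members was placed by the percentile of its median among 10000 random lists of the same size, matched in 20 bins of mean expression. It stood apart below percentile 2.5 or above 97.5, as a description of these libraries. Chromosomes were treated in the same way, using GENCODE 29 positions, found for 95.3% of measured genes. Genes of chromosome Y were left out of the rankings and of the chromosome medians.

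Named genes were chosen by a rule set before the data were examined: NCOA5, the 10 largest log2 ratios in each direction among genes with a symbol and at least 5 FPKM in the larger library, and up to 4 members of each list with the largest ratios in size. Some genes that this rule names are not reported here. The ranking used the 8078 such genes above 0 in both libraries, a restriction added once genes listed at 0 had been seen. Exons of NCOA5 follow its GENCODE 29 transcript. For skipped exons, the share of inclusion was the FPKM of the form with the exon over that of both forms, compared where both forms together had at least 5 FPKM in each library. An exon can enter several pairs of forms. This comparison, and its list of 14 genes spliced differently in epithelial and mesenchymal cells, was added after the data were seen.

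Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The procedure was tested on simulated data for the comparison of the 2 libraries, on 10735 genes: all 200 genes changed 4-fold were recovered, 4 unchanged genes passed the size rule, 20 of 20 lists shifted by 0.5 were called, and 16 of 200 lists of unchanged genes were called. The simulated noise was independent between genes, and its spread (SD 0.298) was taken from these 2 libraries. Changed genes had at least 5 FPKM, and no failed listing was simulated. These counts therefore give no error rate for the real comparison. Alternatives set before the data were examined were a pseudocount of 0.1, scaling by the median ratio, scaling to TPM, the largest event per gene, other minimum levels and fold thresholds, protein-coding genes alone, and the mean over list members. Added after seeing the data were start events alone, end events alone, genes whose sums agree, genes above 0 in both libraries, centring by GC content or transcript length, the exclusion of chromosome 10 genes, and the mean over list members above 0 in both libraries, with random lists drawn from such genes. For the chromosome medians a minimum of 5 FPKM alone was set beforehand, and the other settings were added after seeing the data. GC content was known for every measured member of the lists.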

Results

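Poly-A RNA of LM3, a human hepatocellular carcinoma line, was sequenced in 2 libraries, 1 from wild-type cells and 1 from cells labelled NCOA5 knockout. NCOA5 encodes a coregulator of nuclear receptors such as the estrogen receptor. The series title names epithelial-to-mesenchymal transition, proliferation and migration as the processes of interest. The deposited values were FPKM of transcript start, transcript end and splicing events: 322464 events in wild type, of which 25.3% were above 0, and 322588 in the knockout-labelled library, of which 25.5% were above 0. Sequencing depth was unknown. With 1 library per genotype no difference below has a replicate check, and each one compares these libraries rather than the genotypes.

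The total level of the targeted gene was not lower in the library labelled knockout. NCOA5 (ENSG00000124160.11, chromosome 20, 46060985 to 46089952 on hg38, minus strand) stood at 20.03 FPKM in wild type and 25.4 FPKM in the knockout-labelled library, a log2 ratio of 0.33. The forms of its transcript differed. In the knockout-labelled library, exon 3 of 8 (46070210 to 46070536, 327 coding bases or 109 codons) was listed at 11.9 FPKM in full, or 46.8% of the gene. A form without exon 3 was listed at 9.55 FPKM, or 37.6%. A further 3.97 FPKM, or 15.6%, carried a shortened exon 3 (46070210 to 46070473) that lacked 63 bases, or 21 codons, at its 5′ side. In wild type 0 listed NCOA5 events skipped or shortened this exon. Both the missing exon and the missing 63 bases are multiples of 3 in length. The total level was not lower, while the form with full exon 3 was, at 11.9 FPKM against 20.03 in wild type. A total RNA level alone neither bears out nor contradicts a knockout label, and protein was not measured here. The library is therefore called knockout-labelled throughout, and no direction below can be tied to a loss of total NCOA5 transcript or of its protein.

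**Figure D1:**
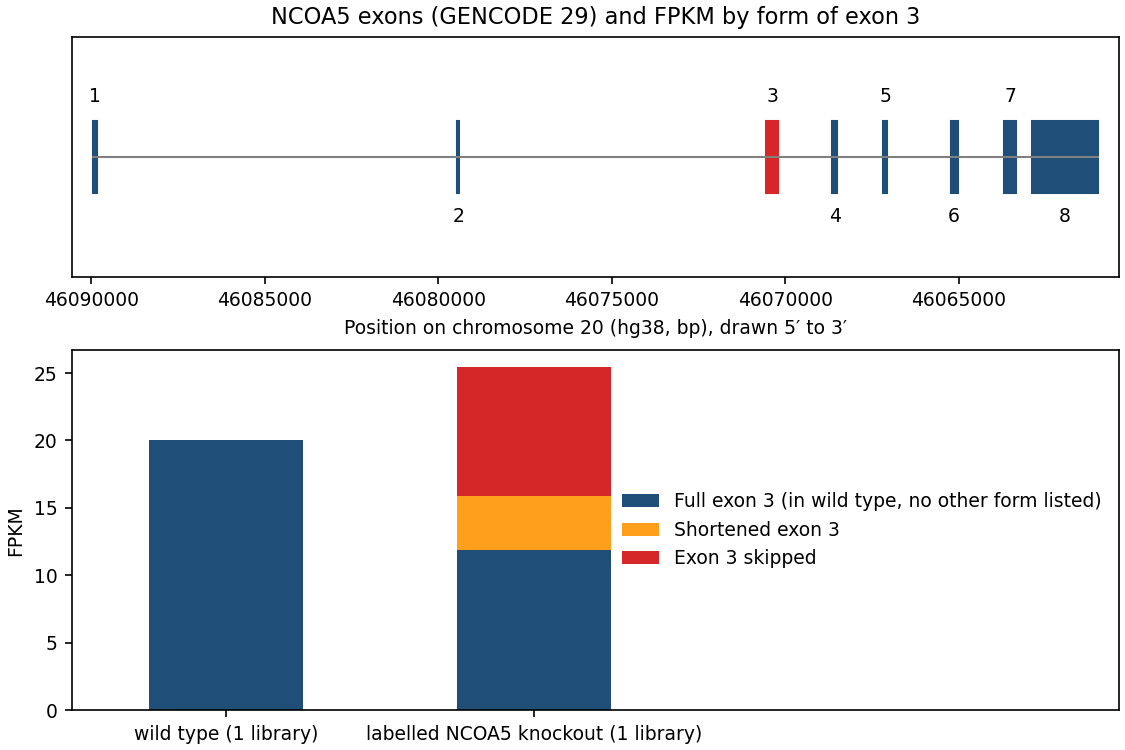
Top, the 8 exons of NCOA5 in GENCODE 29 along chromosome 20 (hg38, in bases), with exon 3 in red. Bottom, NCOA5 level in FPKM in the 2 libraries, divided by the form of exon 3: the wild-type bar reaches 20.03 with no other form listed, and the knockout-labelled bar of 25.4 holds 9.55 without exon 3 and 3.97 with a shortened one.

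Genes were compared by a size rule of 2-fold or more. Of 10909 genes with at least 1 FPKM in either library, 299 were higher and 401 lower in the knockout-labelled library, in which total NCOA5 was not lower, and 85.6% lay within 1.5-fold. Of the higher genes 174 were listed at 0, or had no assigned event, in wild type. Of the lower genes 193 were so in the knockout-labelled library. That left 125 higher and 208 lower genes with both values above 0. The counts depended on the setting: TPM scaling gave 469 higher and 589 lower of 11711 genes, and end events alone 461 higher and 499 lower of 7069. The median log2 ratio of all measured genes was 0.0097, and the correlation of log2 values across genes, which are not independent replicates, was r = 0.933.

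Among genes above 0 in both libraries, the largest positive log2 ratio was that of NBL1, which encodes a secreted antagonist of bone morphogenetic proteins, at 2.87 (5.13 FPKM in wild type, 43.7 in the knockout-labelled library). SNRPD1, a core protein of the spliceosome, followed at 2.83 (21.8 and 161 FPKM). Next came HEBP2, a heme-binding protein, at 2.78, ZNRF1, a ubiquitin ligase, at 2.48, and GNAI3, an inhibitory G protein subunit, at 2.33. SOD3, the extracellular superoxide dismutase, also had 2.33. SAR1B, a GTPase of vesicles leaving the endoplasmic reticulum, had 2.06, IL1RN, the interleukin receptor antagonist, 2.01, MRPL17, of the mitochondrial ribosome, 1.98, and SRSF8, a splicing factor, 1.98. The lowest was ALG14, of protein N-glycosylation, at −3.88 (26.2 and 0.852 FPKM). ALG12, a mannosyltransferase of the same pathway, had −2.53. TNNT1, a troponin of slow skeletal muscle, stood at 114 FPKM in wild type and 15.8 in the knockout-labelled library, a log2 ratio of −2.78. CPA6, a carboxypeptidase, had −2.83, NOS3, the endothelial nitric oxide synthase, −2.68, the noncoding RNA OLMALINC −2.35, RCC2, a protein of chromosome condensation, −2.28, NKAIN3 −2.20 and MCTP1 −2.06. The antisense RNA DSG1-AS1 had −2.10, but strand use was not given in the sources used here, so it cannot be separated from its sense partner. Sums over start and end events agreed within 5% in both libraries for 5 of these 20 genes, namely SRSF8, ALG14, CPA6, OLMALINC and DSG1-AS1. From start events alone the direction turned for GNAI3 (−2.10), SOD3 (−0.02) and ALG12 (0.17), and from end events alone for MCTP1 (0.66).

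**Figure D2:**
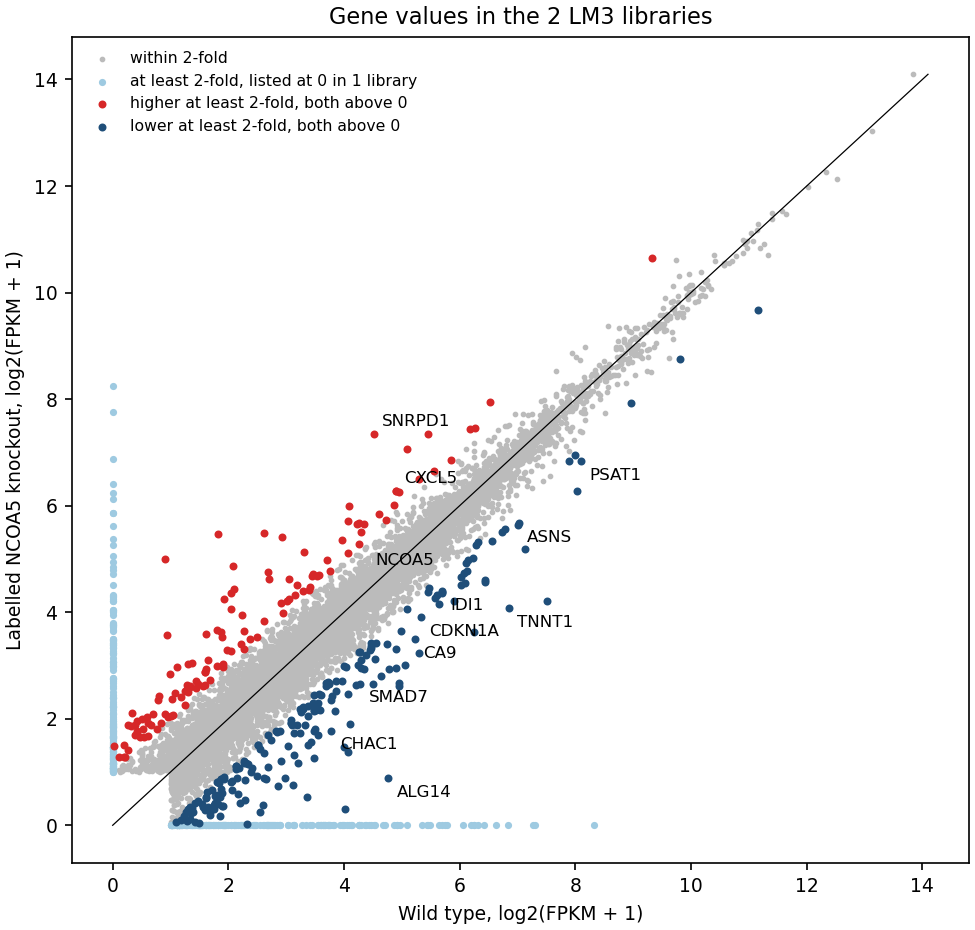
Each point is a gene, with log2(FPKM + 1) in wild type on the x axis and in the knockout-labelled library on the y axis. Red and dark blue points are the 125 higher and 208 lower genes above 0 in both libraries, light blue points are genes at least 2-fold apart and listed at 0 in 1 library, grey points lie within 2-fold, and NCOA5 lies just above the diagonal.

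For the transition between epithelial and mesenchymal states, markers of both states were compared. Of 19 measured epithelial markers, 13 were above 0 in log2 ratio, and 1 with both values above 0 FPKM was higher by at least 2-fold in the knockout-labelled library, in which total NCOA5 was not lower. That was CGN, which encodes the tight junction protein cingulin, with a log2 ratio of 1.05 (6.69 and 14.9 FPKM). The mucin MUC1 was listed at 0 in wild type and at 12.5 FPKM in the knockout-labelled library. The junction proteins TJP3 (1.08 and 2.34 FPKM) and CLDN1 (1.23 and 2.58 FPKM) had 0.68 each, and CDH1, or E-cadherin, 0.34 (2.25 and 3.11 FPKM). In the other direction 6 members were below 0, among them KRT7 (−0.48), JUP (−0.41), CRB3 (−0.29) and TJP1 (−0.24). The list's median of 0.18 lay at percentile 98.4 of 10000 random lists matched on expression. Over members of at least 5 FPKM the median was 0.025, at percentile 60.6, and with genes listed at 0, MUC1 among them, left out, the mean was 0.17, at percentile 97.4. In neither case did the list stand apart.

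Of 21 measured mesenchymal markers, 14 were below 0 in log2 ratio, and 0 with both values above 0 FPKM were lower by at least 2-fold. The collagen cross-linking enzyme LOX was at 2.85 FPKM in wild type and listed at 0 in the knockout-labelled library. MMP14, a membrane-bound matrix protease, had −0.79, SNAI1, a transcription factor that represses E-cadherin, −0.79, and ITGA5, the fibronectin receptor subunit, −0.62. FN1, or fibronectin, had −0.33, CDH2, or N-cadherin, −0.09, and VIM, or vimentin, 0.03. The 7 members above 0 also included COL6A1 (0.47), SPARC (0.47), SNAI2 (0.41) and FBN1 (0.40). FN1, CDH2, VIM, COL6A1, SPARC, SNAI2, FBN1 and, of the epithelial markers, CDH1, KRT7, JUP, CRB3 and TJP1 were named after their values were seen. The median of −0.12 lay at percentile 6.99 and did not stand apart. It did so, below its random lists, in 5 of 14 alternatives, with −0.21 at percentile 0.45 over members of at least 5 FPKM. The TGF-beta pathway, an inducer of the transition, had a median of −0.12 at percentile 2.80, with 17 of 23 members below 0. This list did not stand apart, but did so, below its random lists, in 5 of 14 alternatives, with −0.18 at percentile 0.47 from the largest event per gene. SMAD7, an inhibitor of the pathway, stood at 18.4 and 5.32 FPKM, a log2 ratio of −1.62. INHBE, an activin subunit, had −0.99, ID3, a target gene of bone morphogenetic proteins, −0.72, and SKIL, a corepressor of SMAD proteins, −0.67. The 6 members above 0 included TGFBR1 (0.49), TGFBR2 (0.41) and SMAD4 (0.20), named after their values were seen.

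Genes of migration and invasion showed no common direction, with 18 of 31 members above 0 and a median of 0.03 at percentile 74.3 that turned to −0.08 from end events alone. LAMB3, a chain of laminin, had 0.84, and CDC42, a GTPase of cell polarity, 0.76. ROCK1, a kinase of cell contraction, had −0.81.

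Genes of cell division, read as a measure of proliferation, differed little. In the DNA replication list 27 of 37 members were above 0, with a median of 0.09 at percentile 94.7. The mean was −0.03 with PRIM1, the DNA primase subunit, which was at 52.4 FPKM in wild type and listed at 0 in the knockout-labelled library, and 0.13 without it, at percentile 98.2 of random lists that also leave out genes listed at 0. TYMS, thymidylate synthase, had 0.56, GINS4, of the replicative helicase, 0.62, and CLSPN, of the replication checkpoint, 0.49. In the mitosis list 24 of 38 members were below 0, with a median of −0.05 at percentile 16.4. MAD2L1, of the spindle checkpoint, had 0.96, BUB3, of the same checkpoint, −0.53, KIF11, a spindle motor, −0.51, and NUSAP1, a spindle protein, −0.36. Among 26 cell cycle inhibitors and p53 targets 4 were lower by at least 2-fold and 0 higher, while the median of −0.06 lay at percentile 15.9 and turned to 0.10 from end events alone, and the mean was −0.25, at percentile 4.88, or 0.15 where the random lists leave out genes listed at 0. The 4 lower genes were CDKN1A, the inhibitor p21, at 39.4 and 13.96 FPKM (−1.43), the cell death gene BBC3 (−1.08), the antiproliferative BTG2 (−1.06) and the p53 target TP53INP1 (−1.03). Start and end sums agreed within 5% in both libraries for BBC3 and TP53INP1, but not for CDKN1A or BTG2. Over genes whose sums agree the list's median was 0.08. The 10 members above 0 included TIGAR (0.84) and MDM2 (0.235), named after their values were seen. The total NCOA5 level was not lower in the knockout-labelled library behind these directions.

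The lists that lay farthest from their random lists were those of stress and metabolism. Genes of the unfolded protein and ATF4 response had a median of −0.24, below all 10000 random lists, with 22 of 24 members below 0 and 5 lower by at least 2-fold. CHAC1, which degrades glutathione, had −2.01 and DDIT4, an inhibitor of mTOR signalling, −1.86. ASNS, asparagine synthetase, stood at 129 and 49.8 FPKM (−1.36), and PSAT1, of serine synthesis, at 272 and 113 FPKM (−1.26). Members of the unfolded protein response lay nearer 0 than these. HERPUD1 had −0.34, SDF2L1 −0.23, HSP90B1 −0.12, HSPA5 −0.10 and PDIA4 −0.01. So did further members, SLC3A2 at −0.14, SLC7A11 at −0.11 and SHMT2 at −0.08, and no division of the list was tested. DNAJB9 (0.22) and CRELD2 (0.23) were above 0. These members were named after their values were seen. Genes of hypoxia and glycolysis had a median of −0.31, also below all 10000 random lists, with 22 of 26 members below 0. CA9, a carbonic anhydrase induced by hypoxia, stood at 36.4 and 10.3 FPKM (−1.73), NDRG1 had −0.91 and ALDOC, a glycolytic aldolase, −0.81. ANGPTL4, an inhibitor of lipoprotein lipase, was at 12.2 FPKM in wild type and listed at 0 in the knockout-labelled library. Other members hardly differed, among them SLC2A1 (−0.02), PKM (−0.05) and ENO1 (−0.08). The 4 members above 0 included P4HA2 (0.19), LDHA (0.06) and PGK1 (0.06). These 2 sets of members were named after their values were seen. Genes of cholesterol and fatty acid synthesis had a median of −0.30, again below all 10000 random lists, with 25 of 28 members below 0. IDI1, an isomerase of the mevalonate pathway, stood at 51.0 and 19.9 FPKM (−1.32), and INSIG1, a sensor of sterols, had −1.16. SCD, which makes monounsaturated fatty acids, stood at 174 and 87.7 FPKM (−0.98), and FADS2, a fatty acid desaturase, had −0.68. Over 14 alternatives, the mean over members included, the values ran from −0.49 to −0.19 for the ATF4 list, −0.49 to −0.19 for the hypoxia list and −0.34 to −0.27 for the cholesterol list, and each list stood apart in all 14. The hypoxia mean of −0.49 rests in part on ANGPTL4, and was −0.36 without it. The total NCOA5 level was not lower in the library in which these 3 lists were lower. In all, 4 of 20 lists with a percentile stood apart, and in simulated data 16 of 200 lists of unchanged genes did. The simulated genes varied independently, whereas members of a real list can vary together. The simulated share is therefore not the rate to be had for real lists without a genotype effect.

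**Figure D3:**
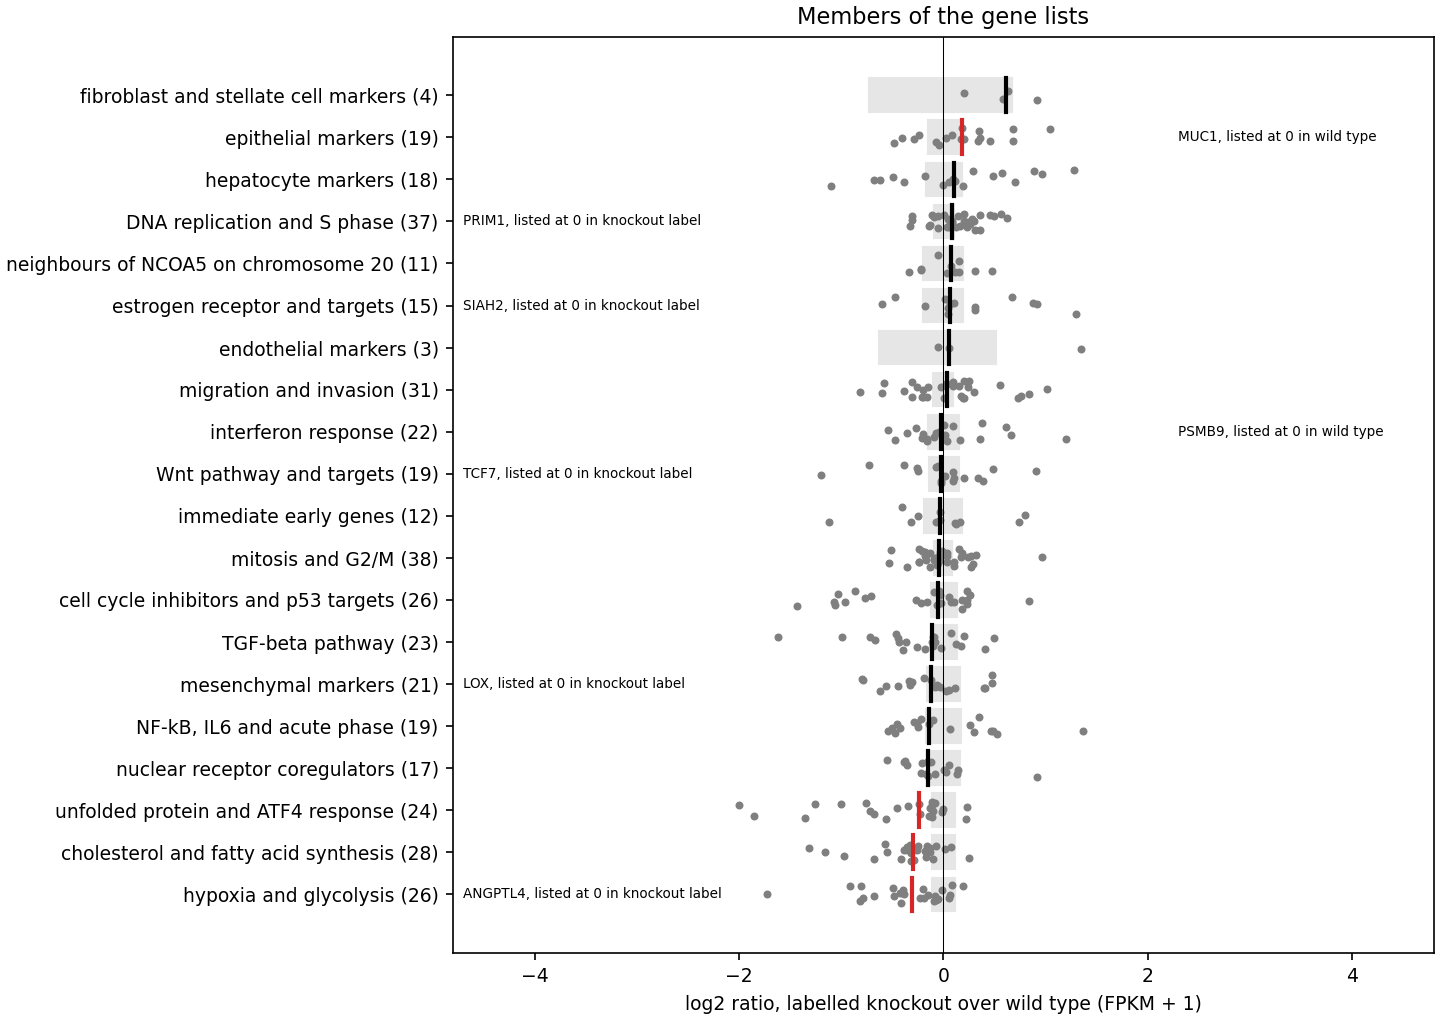
Log2 ratio (FPKM + 1, knockout-labelled library over wild type) of each measured member of 20 gene lists, with the number of members in brackets. Thick bars are list medians, in red for the 4 that stand apart, grey boxes hold the middle 95% of the medians of 10000 matched random lists, and members listed at 0 are named instead of plotted.

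The other lists did not stand apart by their medians. Hepatocyte markers had a median of 0.10 at percentile 85.3 over 18 members, with the fibrinogen chains FGB at 1.27 and FGA at 0.88, TM4SF4 at 0.97 and APOE, an apolipoprotein, at −1.10. The estrogen receptor list had a median of 0.06 over 15 members, and −0.21 over genes whose sums agree. Its mean was −0.02 with SIAH2, which is listed at 0, and 0.24 without it, at percentile 98.2 of random lists that also leave out such genes. In it PDZK1, a scaffold protein, had 1.30, NRIP1, a corepressor, 0.92 and MYBL1 0.88, while SIAH2, a ubiquitin ligase, was at 11.4 FPKM in wild type and listed at 0 in the knockout-labelled library. NF-kB and acute phase genes had a median of −0.15 and a mean of 0.008, and over genes whose start and end sums agree the median was 0.18, at percentile 97.0. With TPM scaling the median was −0.20, at percentile 1.02, where the list stood apart as lower. CXCL5, a neutrophil chemokine, stood at 28.9 and 76.4 FPKM (1.37), CXCL3 had 0.53, IL11 −0.55 and CCL20 −0.50. Interferon genes had a median of −0.02, and a mean of 0.21 with PSMB9 and 0.04 without it, with IFI6 at 1.20, ISG20 at 0.66 and IFIH1 at 0.61, and PSMB9, of the immunoproteasome, listed at 0 in wild type and at 11.7 FPKM in the knockout-labelled library. The Wnt list had a median of −0.02, with NOTUM at −1.20, LGR5 at −0.73 and WNT3 at 0.91, and TCF7 at 14.6 FPKM in wild type and listed at 0 in the knockout-labelled library. Nuclear receptor coregulators had a median of −0.15 at percentile 3.26 and a mean of −0.09, with NRIP1 at 0.92, NCOR1 at −0.55 and NCOA1 at −0.39. The neighbours of NCOA5 on chromosome 20 had a median of 0.07 over 11 members, with ZSWIM3 at 0.47, ZMYND8 at −0.34, SLC35C2 at 0.31 and NCOA3 at −0.22.

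Markers of other cell types had few measured members. Of 12 fibroblast and stellate cell markers 4 were measured, with a median of 0.61 at percentile 96.5: LUM stood at 14.0 and 27.2 FPKM (0.91), COL6A3 had 0.59, DCN 0.63 and LRAT 0.20. The call was the same in 7 of 12 alternatives, and in the others the list stood apart as higher, as with TPM scaling (0.75, percentile 98.9). Of 11 endothelial markers 3 were measured, with a median of 0.06, and KDR, a VEGF receptor, stood at 1.43 and 5.20 FPKM (1.35), ESAM at 0.06 and PECAM1 at −0.05 on the log2 scale. The leukocyte marker measured was LYZ, at 0.914 and 1.77 FPKM (0.53). Of the lists for RNA quality and handling, immediate early genes had a median of −0.03 over 12 members, with NR4A1 at −1.12, FOS at 0.80, KLF2 at 0.74 and FOSL1 at −0.40. Of 22 histone symbols 5 had listed events and 2 were measured, HIST1H2BD at −0.89 and HIST1H2AC at −0.82. Of 13 mitochondrially encoded genes 0 had listed events, so RNA quality could not be assessed from these 2 lists in the event tables.

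By chromosome, genes of chromosome 10 stood out in the knockout-labelled library. Their median log2 ratio was −0.19 over 417 genes, below all 10000 random lists, and 74.1% of them were below 0. All 14 windows of 10 Mb on the chromosome, each with 10 or more measured genes, had a median below 0, from −0.281 to −0.0089, against 31.0% of 268 windows with 10 or more genes on other chromosomes. Chromosome 2, with a median of −0.0041 in all, held a segment as low: its 7 windows from 180 to 250 Mb, with 199 genes, ran from −0.235 to −0.0787. These windows, and those of chromosome 20, were picked out after their values were seen. Chromosome 19 had a median of −0.08 over 700 genes, also below all 10000 random lists, and −0.04 after centring by GC content, at which it still stood apart. Smaller shifts beyond the random lists were found on chromosomes 12 (−0.04) and 16 (−0.02), and in the other direction on chromosomes 1, 4, 5, 6, 7, 8 and 20 (0.04 to 0.08). Those of chromosomes 1, 5, 6, 12, 16 and 20 were lost in at least 1 alternative. Other chromosomes stood apart under an alternative alone, such as 2 with GC centring (−0.03), 13 with the largest event per gene (0.09) and 21 with agreeing sums (0.12). Chromosome 20, which holds NCOA5, had a median of 0.06, but its windows differed: the 2 windows from 0 to 20 Mb were at 0.247 and 0.255, and the window from 40 to 50 Mb, in which NCOA5 lies, was at 0.0324.

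**Figure D4:**
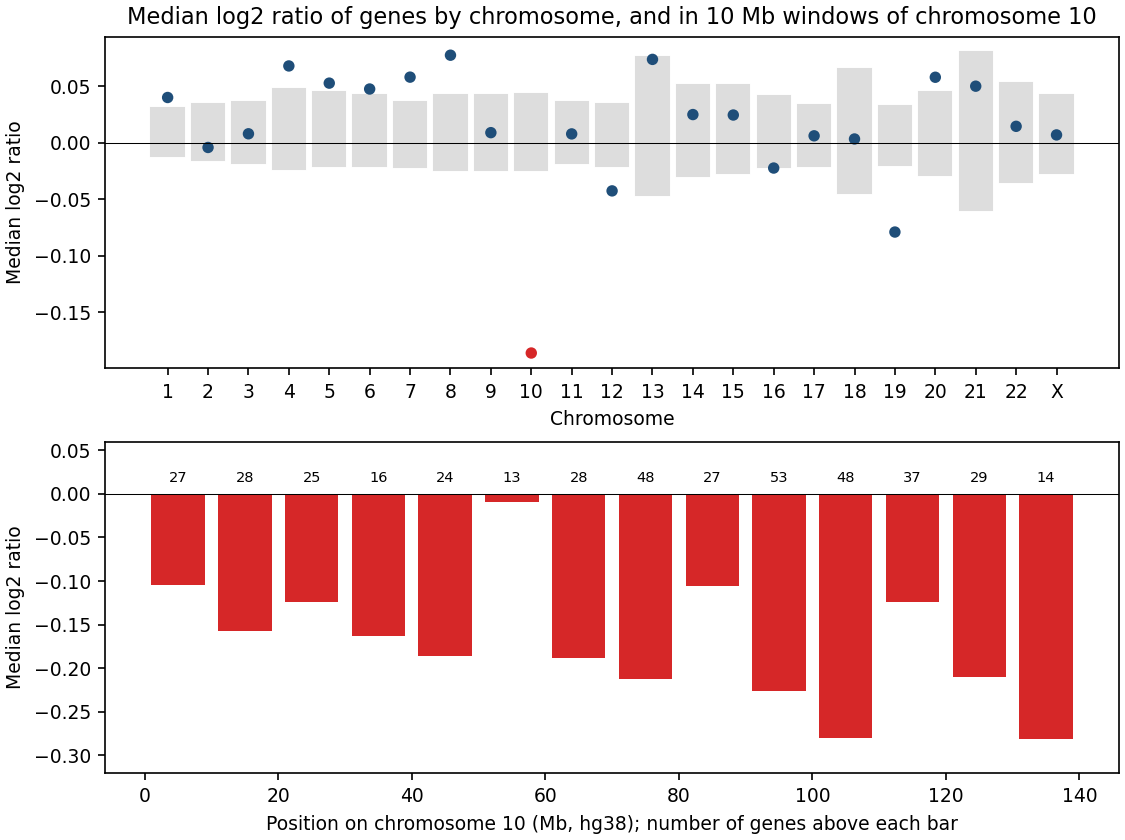
Top, median log2 ratio (knockout-labelled library over wild type) of the measured genes of each chromosome, with grey boxes for the middle 95% of 10000 matched random lists. Bottom, medians in 10 Mb windows of chromosome 10 with the number of genes above each bar; all 14 lie below 0.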

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

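Settings based on start or end events, on agreement of their sums, on genes above 0, on GC content, on length or on chromosome 10, and those for chromosomes other than a minimum of 5 FPKM, were chosen after seeing the data. Leaving out a library was not possible with 1 per genotype. The total NCOA5 level stayed higher in the knockout-labelled library in 7 alternatives (log2 0.32 to 0.36). The largest event, start events, end events and agreeing sums could not move it, since its start, end and largest values were equal in each library. Against 299 higher and 401 lower genes, a minimum of 5 FPKM gave 155 and 224, agreeing sums 128 and 194, genes above 0 in both libraries 125 and 208, a threshold of 1.5-fold 693 and 875, and 4-fold 100 and 134, each by its construction. TPM scaling raised the values, so that 11711 genes passed the minimum and the pseudocount weighed less, and it gave 469 higher. A pseudocount of 0.1 gave 435 higher. How much of the TPM count comes from this was not tested, nor was the cause for end events alone (461 higher). Dropping the minimum level changed nothing, since a 2-fold ratio with a pseudocount of 1 already needs 1 FPKM. The stress, hypoxia and sterol lists stood apart in all 14 alternatives, and chromosome 10 in all 11 (−0.21 to −0.17). Epithelial markers did not at 5 FPKM (0.025), where low members drop out, or as a mean without genes listed at 0 (0.17), where MUC1 does. Lists that stood apart under an alternative alone, with the cause not tested, were: mesenchymal markers with the largest event per gene (−0.19), at 5 FPKM (−0.21), with end events (−0.29), agreeing sums (−0.33) and GC centring (−0.20); TGF-beta with the largest event (−0.18), end events (−0.19), GC centring (−0.15), length centring (−0.14) and as a mean without genes listed at 0 (−0.24); replication without genes listed at 0 (0.10, 0.13 as a mean) and with GC centring (0.10); p53 targets (−0.25, with 0 members but random genes left out) and estrogen receptor (0.24) as means without genes listed at 0; NF-kB with TPM (−0.20, against 0.18 with agreeing sums); and the 4 fibroblast markers with TPM (0.75), the largest event (0.63), end events (0.63) and genes above 0 (0.61, 0.58 as a mean). Of the 16 lists that did not stand apart, 7 changed sign in at least 1 alternative: NF-kB, p53 targets (−0.06, 0.10 with end events), estrogen receptor (0.06, −0.21 with agreeing sums), migration (0.03, −0.08 with end events), Wnt (−0.02, 0.03 with GC centring), interferon (−0.02, 0.21 as a mean, 0.04 without PSMB9, listed at 0) and replication (0.09, −0.03 as a mean, through PRIM1, listed at 0). Called values that changed sign were chromosome 16 with TPM (0.0034), where the median of all genes also moved from 0.0097 to 0.0295, GNAI3 (−2.10), SOD3 (−0.0225) and ALG12 (0.17) with start events, and MCTP1 (0.66) with end events. Unknown depth limits every value, low ones most.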

Other observations

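In genes known to be spliced differently in epithelial and mesenchymal cells, 57 pairs of forms with and without an exon were compared, over 53 exons of 13 genes. In 18 pairs inclusion lay between 1 and 99% in at least 1 library, and 9 of these differed by more than 10 percentage points, 6 with higher and 3 with lower inclusion in the knockout-labelled library. The higher pairs were in NUMB, SLK and TCF7L2, and the lower in ARHGEF11, ENAH and MAGI1. NUMB and TCF7L2 entered with more than 1 exon each, so pairs are not independent. The 2 pairs that differed by at least 20 points were lower. In ENAH, an actin regulator, inclusion of the exon at 225517196 to 225517306 on chromosome 1 was 100% in wild type and 79.2% in the knockout-labelled library. For the ENAH exon of 63 bases at 225504991 to 225505053 it was 11.7% and 8.5%. In MAGI1, a junction scaffold, inclusion of the exon at 65448022 to 65448057 on chromosome 3 was 100% and 69.5%. Both MAGI1 forms together had 5.41 and 5.28 FPKM, just above the minimum of 5. The list names genes, so an exon compared need not be one known to differ. Over all genes, 83.3% of 12668 such pairs had shares of inclusion within 1 point, and 5.94% differed by at least 20 points, 403 with higher and 350 with lower inclusion in the knockout-labelled library. Most pairs were within 1 point of 0 or 100% in both libraries, and of the 2218 with intermediate inclusion in at least 1 library 58.7% differed by more than 10 points. That share is raised by the choice of pairs, since an exon at 0 or 100% enters it by differing.

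Some well-expressed genes were listed at 0, or had no assigned event, in 1 library: 47 genes had at least 20 FPKM in the other. HSPE1, a mitochondrial chaperonin, stood at 320 FPKM in wild type and was listed at 0 in the knockout-labelled library. PHLDA1, a regulator of cell death, stood at 113 FPKM in wild type and was likewise listed at 0. SSX1, a cancer-testis antigen, was listed at 0 in wild type and at 116 FPKM in the knockout-labelled library, and UGT1A1, the bilirubin glucuronosyltransferase, at 0 and 83.7 FPKM. These 4 genes were named after their values were seen.

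The tests in the next paragraphs were all chosen after the patterns were seen. In the library labelled knockout, 53.2% of NCOA5 FPKM lay in forms with exon 3 skipped or shortened, and 0 wild-type events showed such forms. That would argue against swapped labels if the forms came from an edit, which the tables do not settle. Differences in transcript assembly between libraries may also give such a listing: 82 of 7939 genes, or 1.03%, listed an exon with 25 to 75% skipping in this library alone, NCOA5 among them, and in wild type alone the share was 1.13%. Such a listing was uncommon, and assembly, swapped labels and an edit at exon 3 cannot be told apart without reads across the exon, which were not analysed here.

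The lists of stress, hypoxia and sterol genes were lower together in the knockout-labelled library. GC content does not account for the whole of it, since after GC centring the median nearest 0 was −0.19 (the stress list) and all 3 lists stood apart. Chromosome 10, which holds 7 of the 26 hypoxia genes measured, as well as IDI1, SCD and DDIT4, does not either, since without its genes the median nearest 0 was −0.19 (the hypoxia list). The culture state at harvest, such as cell density or the age of the medium, could also lower these genes, and with 1 library per genotype it cannot be told apart from genotype. A response to altered NCOA5 remains open as an untested hypothesis.

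The lower level of chromosome 10 genes ran along the whole chromosome. The median after GC centring was −0.21, which argues against GC content as the cause. A few strongly lower genes would hardly move a median over 417 genes. That 74.1% of genes were below 0 follows largely from this median and is no separate support. A lower copy number may be a cause but cannot be told apart from others here: RNA in proportion to the loss of 1 copy of 3 in every cell would give −0.58, the chromosome's median was −0.19, and DNA, which could settle it, was not analysed. Runs of windows were not limited to this chromosome and went both ways, with 7 below 0 on chromosome 2 from 180 to 250 Mb (−0.235 to −0.0787), and above 0 10 on chromosome 7 from 0 to 100 Mb (0.0354 to 0.224) and 11 on chromosome 8 from 40 to 150 Mb (0.0186 to 0.241). A clonal difference in the line and an effect of the genotype both stay open.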
